A study of Mus musculus with 2 samples.

How the data were processed

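Gene expression was measured by RNA sequencing in regulatory T (Treg) cells from mouse spleen. Per the labels' protocols, the host mice carried a Foxp3 reporter allele (DTR/GFP), in which cells that express Foxp3, the transcription factor that defines Treg cells, carry a green fluorescent protein (GFP). Cells positive for CD4 and FOXP3-GFP were sorted from mice with acute myeloid leukemia and from healthy mice given phosphate-buffered saline. Per the labels' protocols, libraries were made from 1 µg of total RNA and sequenced on a BGISEQ-500 instrument. Each group held 1 library, so samples were grouped by the disease state and title in the labels, and the comparison has no replicate check. Whether a library pooled cells of several mice, and whether RNA was selected for poly(A) tails, is not given in the sources used here.

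Per the submitters' processing notes, Bowtie2 2.2.5 and RSEM were used upstream; the RSEM version, the genome build and the annotation release are not given in the sources used here, and no coordinates are printed. Per the file headers, each deposited table holds an expected count, an estimated number of reads or fragments per gene that RSEM assigns to genes and that need not be whole. The deposited FPKM value (fragments per kilobase of transcript, scaled to 1000000 fragments) was, per the file headers, a separate column, given to 2 decimals with 0.01 as the lowest listed value. A gene length column was also deposited and was used only to check how count and FPKM were related. The library totals implied by that relation lay near the summed estimated counts of 8929601 and 8897162, so FPKM was scaled by the library's own total. RSEM shares out reads that match several genes by estimate, so values of near-identical genes are uncertain.

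The tables name genes by NCBI Gene ID. Of 23248 IDs listed in either library, 21713 matched a symbol in the RefSeq gene table by ID and 22 by transcript accession, while 1513 had no symbol and held 0.92% of reads in the healthy and 1.04% in the leukemia library. The RefSeq table, of assembly GRCm38.p6, served only for names and gene types. A gene listed in 1 table alone was taken as 0 in the other; there were 1689 such genes in the healthy and 1929 in the leukemia library, with median FPKM of 0.09 and 0.11.

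The measure was log2((FPKM leukemia + 1) / (FPKM healthy + 1)), with a pseudocount of 1 FPKM, over genes at 1 FPKM or more in at least 1 library. It understates the difference of genes with low values. A gene was called higher or lower in the leukemia library at a log2 ratio of 1 or more, or of -1 or less, which is a rule of size and not a test. For single genes, an exact (Clopper-Pearson) 95% interval of the read ratio, each count divided by its library's total, was computed from the estimated counts rounded to whole numbers. These intervals and the limits from 0 reads cover counting error only and compare the libraries, not the conditions. A count of 0 was set to 3 reads for a lower bound of a fold, which leaves out the counting error of the other library and corresponds to 0.336 of every 1000000 reads in the healthy and 0.337 in the leukemia library. With 10 reads in each library the interval of the read ratio runs from 0.375 to 2.69. With 100 reads it runs from 0.753 to 1.34, and with 1000 reads from 0.918 to 1.10.

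Before the data were examined, 45 gene lists were fixed. They cover Treg identity, T cell function, processes, metabolism, handling stress, and other cell types that the sort could hold. Each list is given with the median log2 ratio of its members at 1 FPKM or more and a 95% order-statistic interval of that median over members. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is not a p-value. The named genes followed a rule fixed before the data were examined. It took sort checks (Foxp3, Cd4, Il2ra and Cd8a among them) and the 12 highest and 12 lowest log2 ratios among genes at 10 FPKM or more in the higher library. Predicted genes, microRNAs, small nucleolar RNAs, other provisional names and numbered pseudogenes were left out of that ranking. It also took up to 4 members of each list with the largest absolute log2 ratio, and all measured chemokine receptors. Some genes that this rule names are not reported here.

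The alternatives chosen before the data were examined were a pseudocount of 0.1 FPKM, rescaling FPKM to 1000000 per library (TPM), and division by the median ratio. Further ones were estimated counts as CPM with TMM scaling in edgeR, no filter or a filter of 5 FPKM, and rescaling after leaving out other-cell, immunoglobulin and mitochondrially encoded genes. The CPM values were not divided by gene length and took a pseudocount of 1 CPM. The mitochondrially encoded list matched 0 symbols, so no gene was left out through it. After seeing the data, a scaling centred on the T cell receptor signalling list and a condition that the read-ratio interval leave out 1 were added.

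The calling rule and the read-ratio interval were tested on data simulated from the mean levels of both libraries, with 13505 genes at 1 FPKM or more. Of 100 genes simulated at 4-fold higher, 99 were called higher, and of 100 at 4-fold lower, 86 were called lower. Among 13308 unchanged genes, 121 were called either way by counting error alone. The read-ratio interval held the true ratio for 95.6% of unchanged genes. The interval of a median was tested apart, on 18 independent normal values not drawn from the libraries. It held the true median in 96.8% of these simulations. Members of a gene list can vary together, so this coverage need not hold for the lists. Of 20 simulated lists without a shift, 2 fell outside the middle 95% of random lists, in a simpler version of the percentile with fewer random lists. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, with edgeR 4.0.16 in R 4.3.3 for the TMM factors only.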

Results

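The transcriptome of splenic Treg cells, CD4 T cells that restrain other immune cells, was compared between mice with acute myeloid leukemia and healthy mice, with 1 library in each group and hence no replicate check. Leukemia was started by transplanting 800000 leukemia cells without irradiation into mice aged 6 to 8 weeks. Treg cells were sorted at day 18, and leukemia mice survived for 30 to 40 days. Healthy mice received phosphate-buffered saline. The healthy library held 8929601 estimated reads on 21319 listed genes and the leukemia library 8897162 on 21559, a ratio of 0.996, so depth differed little. At 1 FPKM or more there were 12874 genes in the healthy and 13182 in the leukemia library. The 10 genes with most reads took 4.65% and 4.66% of reads.

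The comparison asked how Treg cells of leukemia mice differ in gene expression from those of healthy mice. The leukemia library held high levels of genes of immature myeloid cells, such as Mpo and Cd34, and higher levels of cell division genes, while T cell genes were slightly lower as a group and type I interferon response genes were lower. Of 13717 genes at 1 FPKM or more in either library, 898 were at least 2-fold higher in leukemia, 267 were at least 2-fold lower, and 12552 were under 2-fold either way. Here and below, 2-fold refers to log2(FPKM + 1), which understates ratios of genes with low values. The 95% interval of the read ratio left out 1 for 821 of the higher and 169 of the lower genes. Protein-coding genes made up 716 of the higher but only 113 of the lower genes, which also included 58 microRNA genes, 17 small nucleolar RNA genes and 38 long non-coding RNA genes. The higher genes included 36, 20 and 64 of these classes. Shares of these classes among all 13717 genes were not computed, so the counts do not show whether a class was over-represented. Across 8561 genes at 5 FPKM or more in both libraries, log2 FPKM had a Pearson r of 0.95 across genes, which are not independent replicates. The median log2 ratio of all genes was 0.02. Centring on the T cell receptor signalling genes, a scaling chosen after seeing the data, moved that median to 0.43 and gave 1805 higher against 155 lower genes. Directions below are relative to the deposited scale, and values "centred on T cell genes" are given beside many of them.

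**Figure D1:**
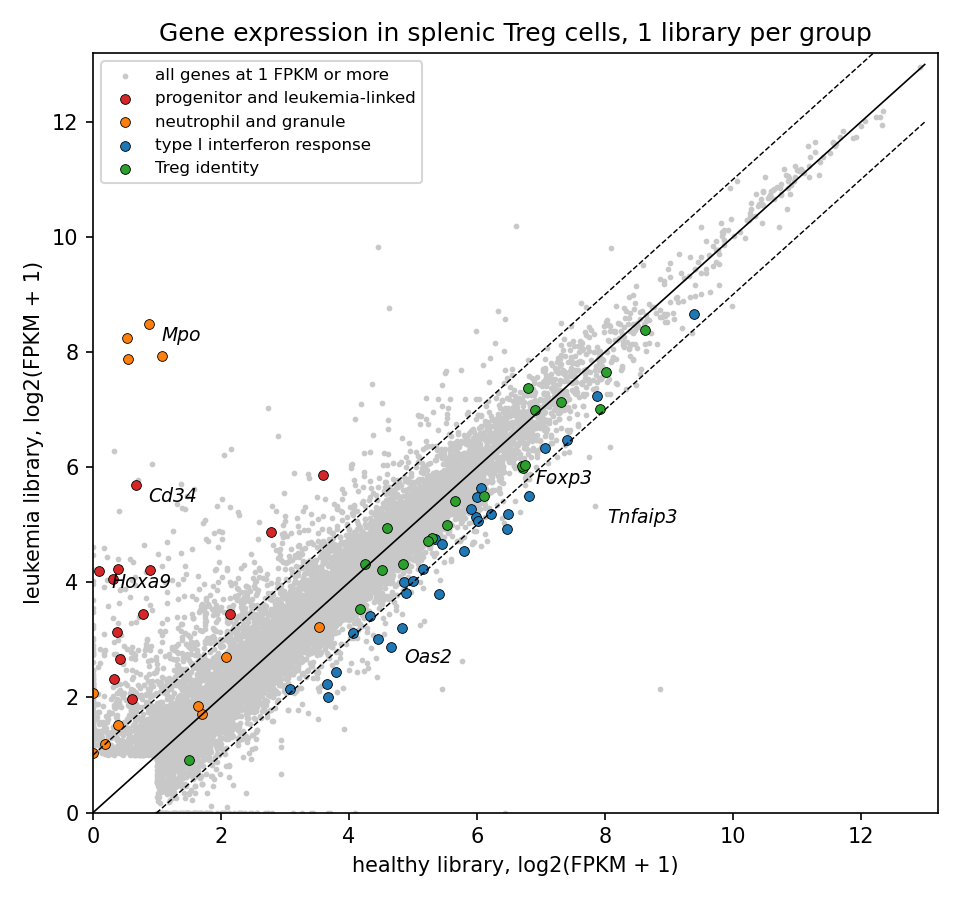
Gene expression in the healthy (x axis) and leukemia (y axis) libraries as log2(FPKM + 1), with each point a gene at 1 FPKM or more in either library; the solid line marks equal values and dashed lines 2-fold differences. Progenitor and granule genes such as Mpo (0.83 and 357 FPKM) lie far above the line, and the 30 type I interferon response genes lie below it.

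Transcripts of the sort gate, Foxp3 and Cd4, and of the further sort check Il2ra were present in both libraries. Foxp3 (NCBI Gene 20371) stood at 104 FPKM in the healthy and 62.7 FPKM in the leukemia library, a read ratio of 0.602 with a 95% interval of 0.571 to 0.636. Cd4 (12504), the co-receptor used for sorting, was at 267 and 184 FPKM, and Il2ra (16184), the high-affinity interleukin-2 receptor chain, at 104 and 64.1 FPKM. Their log2 ratios of -0.72, -0.54 and -0.69 were under 2-fold. Cd8a (12525), a marker of T cells outside the gate, was low in both libraries, at 1.33 and 1.28 FPKM. The macrophage complement genes C1qa, C1qb and C1qc, picked after their values were seen, were not low. They stood at 173, 165 and 167 FPKM in the healthy and 96.6, 82.9 and 87.4 FPKM in the leukemia library. RNA of cells outside the gate is thus not excluded in either library.

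Treg identity genes were slightly lower together. The 20 measured members had a median log2 ratio of -0.52 (95% interval -0.61 to -0.23), below all 10000 random lists, and none was 2-fold different. The 4 with the largest ratios were Ctla4, an inhibitory receptor (241 and 128 FPKM in healthy and leukemia, log2 ratio -0.91), Foxp3, Ecm1 (-0.72) and Il2ra. T cell receptor complex and signalling genes had a similar median of -0.45 (-0.54 to -0.36) over 18 members, with 17 below 0 and none at 2-fold, for example Themis (-0.79), the phosphatase gene Ptprc (-0.68) and the kinase Prkcq (-0.63). Genes of resting T cells had a median of -0.55 (-0.63 to -0.24) over 20 members, also with none at 2-fold. Among them were S1pr1, which guides T cells out of lymphoid tissue (121 and 62.9 FPKM, -0.93), the transcription factors Foxo1 (-0.89) and Klf2 (-0.81), and Lef1 (-0.64). The 14 genes listed as conventional CD4 T cell genes low in Treg cells had a median of -0.47 (-0.68 to -0.24). Among them were Slc28a2b (-0.79), Nsg2 (-0.68) and Actn1 (-0.63), at 22.5, 114 and 71.9 FPKM in the healthy library, where Foxp3 was at 104 FPKM. The lists share genes: 9 Treg identity, 12 resting T cell and 10 conventional CD4 T cell genes were also in another list. For T cell receptor signalling it was 1 gene. The similar medians are therefore not independent of each other. In the same leukemia library, progenitor genes had a median log2 ratio of 2.67, and centring on T cell genes brought the Treg identity median to -0.08.

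Activated Treg genes had 27 members, of which 20 were also in another list. Their median was -0.05 (-0.29 to 0.19) on the deposited scale, and 0.40 (0.14 to 0.63) when centred on T cell genes. Centring put the median of all genes at 0.43, so 0.40 shows no rise above them. Among random lists on the deposited scale, the activated Treg median lay at percentile 21.1. Only Lgals1, which encodes the lectin galectin-1, was 2-fold higher among them (273 and 897 FPKM, log2 ratio 1.71), while Il1rl1 (-0.66), Itgae (-0.64) and Rora (-0.59) were under 2-fold. Suppressive effector genes had a median of -0.21 (-0.54 to 0.42) over 16 members, -0.0067 with a filter of 5 FPKM, and 0.17 when centred on T cell genes. In that list, Lgals1 and Il12a were higher and Areg, encoding amphiregulin, was lower (4.91 and 1.70 FPKM, -1.13, or -0.83 when centred). Il12a, which encodes the subunit shared by interleukin-12 and interleukin-35, was unlisted in the healthy library and had 8.22 FPKM on 92 reads in leukemia, at least 30.8-fold higher with the 0 set to 3 reads, while the exact interval of the read ratio starts at 24.5. Inhibitory receptors and ligands had a median of -0.31 (-0.67 to 0.38) over 14 members, -0.53 with a filter of 5 FPKM, and 0.05 centred. Among these Cd244a was higher (1.09 and 3.71 FPKM, 1.17), and Cd96 (-0.70) and Cd200r1 (-0.67) were under 2-fold. Mpo reached 357 FPKM in the same leukemia library. Bulk RNA does not show whether Treg cells or other cells held the added Lgals1, Il12a and Cd244a transcripts. Costimulatory receptors had a median of -0.36 (-0.47 to -0.05) over 14 members with none at 2-fold, or 0.09 centred, with Cd226 at -0.60, Cd2 at -0.59, Slamf1 at -0.47 and Slamf6 at -0.46.

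Early T cell receptor response genes had 3 of 15 members lower and a median of -0.38 (-0.99 to -0.21), or 0.07 when centred on T cell genes. Tnfaip3, which encodes the NF-kappaB inhibitor A20, was among the lowest of all genes, at 228 FPKM in healthy and 39.0 FPKM in leukemia Treg cells, a read ratio of 0.172 (0.163 to 0.181). Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, was lower at 101 and 36.4 FPKM (-1.45), as was Nfkbiz at 52.3 and 25.3 FPKM (-1.02), whose call ended when centred (-0.58). The activation marker Cd69 lay just under 2-fold (-0.99). Of 22 immediate early and heat shock genes that handling can induce, 5 were lower in the same library and 8 lay above 0. Their median was -0.17 (-0.96 to 0.11). The lower ones included Dusp1 (-1.57, or -1.12 centred), Fos (-1.40, or -0.95), Fosb (-1.28, or -0.84) and Klf6 (-1.28, or -0.83). Interleukin-2 and STAT5 pathway genes had a median of -0.30 (-0.54 to -0.05) over 15 members, or 0.14 centred. The kinase Pim1 was the 1 lower member (163 and 75.0 FPKM, -1.11, or -0.66 centred), and Jak1 (-0.63) and Il2rg (-0.54) were under 2-fold. TGF-beta pathway genes had a median of -0.39 (-0.61 to 0.00) over 13 members with none at 2-fold, and 0.00 centred, with Skil at -0.85, Smad7 at -0.77, Lrrc32 at -0.61 and Tgfbr2 at -0.60. Helper cytokine genes had a median of -0.16 over 8 members, with a wide interval of -1.18 to 0.40, and 0.26 centred. Ifng, encoding interferon-gamma, was lower (12.9 and 5.92 FPKM, -1.01, or -0.61 centred), and Il4 was lower on 9 reads against 1 (-1.18, or -0.86 on TMM-scaled counts, which ended the call), while Il21 (0.40) and Ltb (-0.31) were under 2-fold. Lineage-defining transcription factors had a median of -0.19 (-0.49 to 0.20) over 15 members, or 0.22 centred. Bhlhe40 was lower at -1.05 (-0.63 centred), Zeb2 was at 0.97 on this scale but had a read ratio of 2.51 (2.05 to 3.08), and Gata3 was at -0.57.

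Chemokine receptors, which direct migration, mostly stayed under 2-fold, with a median of -0.20 (-0.55 to 0.26) over 16 members, -0.06 with no filter on low values, and 0.22 when centred on T cell genes. Ccr1, at 0.28 and 3.66 FPKM, and Cx3cr1, at 1.79 and 7.49 FPKM, were higher in leukemia, with read ratios of 13.3 (6.22 to 34.1) and 4.19 (3.14 to 5.60). Both are also expressed by myeloid cells. Ccr3, an eosinophil and basophil receptor, was lower at 19.4 and 6.26 FPKM, with a read ratio of 0.336 (0.283 to 0.398). Receptors used by Treg cells lay closer to even, with Ccr7 at 127 and 81.1 FPKM (log2 ratio -0.64), Cxcr4 at 39.3 and 52.5 FPKM (0.41), Cxcr3 at 47.0 and 46.9 FPKM (0.00) and Cxcr5 at 33.3 and 30.6 FPKM (-0.12). Ccr4 (-0.32), Ccr6 (-0.29), Cxcr6 (-0.29), Cxcr2 (-0.30), Ccr8 (0.23) and Ccr2 (0.03) were also under 2-fold, as were Ccr9 (-0.69) and Ccr10 (-0.55) at low levels. Adhesion and homing genes had a median of -0.31 (-0.52 to -0.20) over 17 members, or 0.14 centred. In this list Vcam1 was lower (111 and 46.2 FPKM, -1.24, or -0.80 centred). Vcam1 is also expressed by splenic macrophages. The macrophage genes Spic (-1.17, or -0.74 centred), Mrc1 (-1.39, or -0.97) and Hmox1 (-1.08, or -0.63), picked after their values were seen, were lower in the same library. Centred, they stayed below 0 but under 2-fold.

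**Figure D2:**
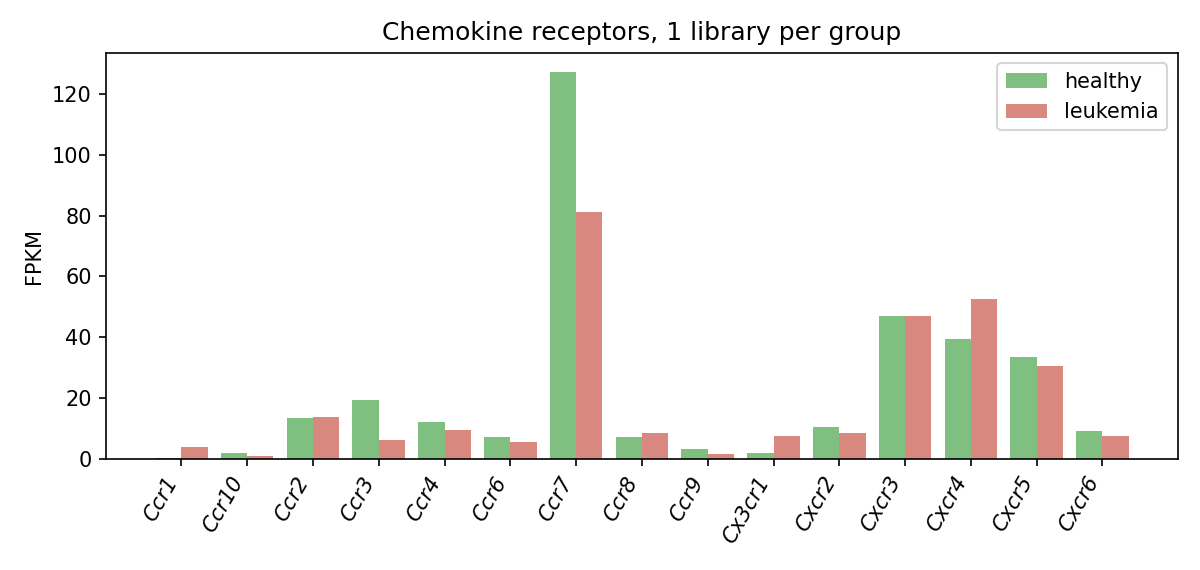
FPKM of the chemokine receptors named in the text, as bars for the healthy and leukemia libraries with 1 library each and no error bar. Ccr7 was the most abundant (127 and 81.1 FPKM), and Ccr3 showed the only lower call (19.4 and 6.26 FPKM).

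Genes of neutrophil granules and of myeloid progenitors had the highest ratios. Ctsg (13035), Mpo (17523), Prtn3 (19152) and Elane (50701), which encode the primary granule proteins cathepsin G, myeloperoxidase, proteinase 3 and neutrophil elastase, stood at 0.45, 0.83, 0.46 and 1.12 FPKM in the healthy library and at 304, 357, 234 and 242 FPKM in leukemia. The read ratio of Mpo was 433 (270 to 743), on 17 and 7327 reads. Other genes in the top 12 were Hp, encoding haptoglobin (3 and 927 reads), Plac8 (21.0 and 905 FPKM), Rab44 (0.90 and 65.8 FPKM), F13a1 (0.63 and 54.2 FPKM), Cd34 (0.59 and 50.6 FPKM) and Adgrg3 (0.32 and 37.0 FPKM). Clec2m was unlisted in healthy and at 21.2 FPKM in leukemia, at least 107-fold higher with the 0 set to 3 reads and with an exact interval from 86.3, and Bex6 had 1 and 200 reads, a ratio of 201 (35.6 to 7968).

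The neutrophil and granule list had 8 of 12 members higher and a median of 1.08 (0.21 to 7.33). Its median was 3.03 with a pseudocount of 0.1 FPKM, and 7.09 over the 6 members left by a filter of 5 FPKM. With no filter it was 0.78 over 17 members. Of the 12, 5 reached 1 FPKM in the healthy library. Genes of later neutrophil stages had few reads in both libraries, with S100a8 on 1 and 6 reads, S100a9 on 1 and 3, Ltf on 0 and 1 and Ngp on 2 and 2. All 13 hematopoietic progenitor and leukemia-linked genes at 1 FPKM or more were higher, with a median of 2.67 (2.01 to 3.84), and 10 of them reached 1 FPKM in the leukemia library alone. The other members of the list, under 1 FPKM in both libraries, were not higher: Hlf had 25 and 12 reads, Mecom 11 and 12, and Irx5 1 and 0, and with no filter the median was 2.25. Besides Cd34, a progenitor surface protein, these included the homeobox gene Hoxa9 (0.07 and 17.3 FPKM, 4.10), the cytokine receptor Flt3 (0.31 and 17.8 FPKM, 3.84) and Mef2c (0.24 and 15.6 FPKM, 3.74). Monocyte and macrophage genes went both ways, with 5 of 24 higher and 2 lower and a median of -0.04 (-0.83 to 0.79). Centred on T cell genes, 8 were higher and 0 lower, with a median of 0.38, against 0.43 for all genes. Higher were Ly6c2 (23.7 and 437 FPKM, 4.15), the myeloid transcription factor Spi1 (9.40 and 55.1 FPKM, 2.43), Tyrobp (1.70) and Ms4a6c (1.61), the last close to other members of its gene family. Named after their values were seen, Itgam was also higher (1.01 and 5.01 FPKM, 1.58), and the lower members were Vcam1 and Hmox1 (151 and 71.0 FPKM, -1.08, or -0.63 centred).

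The lowest ratios included several genes whose reads RSEM has to share among near-identical copies, and these are uncertain. Tmem254c was at 42.7 and 3.44 FPKM while its copy Tmem254b was at 3.04 and 42.6 FPKM, so that their sums were 45.7 and 46 FPKM. The same caution holds for the class I histocompatibility genes H2-Q9 (53.4 and 5.24 FPKM), H2-Q10 (14.2 and 1.75 FPKM) and H2-Bl (11.7 FPKM and unlisted, at least 44.7-fold lower with the 0 set to 3 reads, exact upper limit of the read ratio 0.0278), for Ifit3b, and for the pseudogene Bnip3l-ps (-1.69). A pair of genes with no symbol headed the lower genes: NCBI Gene 101056305, at 465 and 3.45 FPKM, and NCBI Gene 105247284, at 85.7 FPKM and unlisted, at least 40.3-fold lower with the 0 set to 3 reads and with an exact upper limit of the read ratio of 0.0311. Besides Tnfaip3, lower genes without this limit were Sik1, a salt-inducible kinase (35.1 and 9.05 FPKM, -1.84), Oas2 (24.3 and 6.37 FPKM, -1.78) and Ppp1r15a, which encodes the stress-induced phosphatase subunit GADD34 (271 and 80.9 FPKM, -1.73).

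Cell division genes were higher together in the leukemia library. Of 24 mitotic genes 19 were higher and none lower, with a median of 1.43 (1.11 to 1.54), and of 23 DNA replication genes 18 were higher and none lower, with a median of 1.45 (1.15 to 1.70), both above all 10000 random lists. Centred on T cell genes, 24 and 22 were higher. Examples were the mitotic kinase Aurkb (4.12 and 18.8 FPKM, 1.95), Ccnb2 (1.90), Tpx2 (1.61), Cdk1 (2.99 and 10.8 FPKM, 1.57), Uhrf1, which maintains DNA methylation (6.23 and 36.9 FPKM, 2.39), Tk1 (1.99), Chaf1a (1.94) and Cdc6 (1.91). Histone genes, matched by symbol and mostly without poly(A) tails, had 5 of 11 members higher and a median of 0.80 (-0.02 to 1.37). It was 0.46 with a filter of 5 FPKM and 1.40 with a pseudocount of 0.1 FPKM. Levels were low, such as 4.70 and 14.3 FPKM for H4c9. The other higher members, H1f10, H3c3, H4c3 and H3c8 (named after its value was seen), had at most 31 reads, and the calls of H3c3 and H4c3 ended on TMM-scaled counts. These genes were higher in the same library as the progenitor genes.

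Several groups of biosynthetic and energy genes had medians slightly above 0, with few members at 2-fold on the deposited scale. Among random lists, the medians of ribosome biogenesis and oxidative phosphorylation lay at percentile 100, and proteasome, glycolysis, fatty acid, cholesterol and uptake genes at 99.98, 99.93, 99.59, 98.31 and 97.87. Hypoxia, tricarboxylic acid cycle and ribosomal protein genes, at 96.46, 90.51 and 82.43, lay within the middle 95% of random lists. Centred on T cell genes, 8 ribosome biogenesis, 8 oxidative phosphorylation, 6 glycolysis and 5 fatty acid genes were 2-fold higher, with medians of 0.95, 0.85, 0.85 and 0.76. Progenitor genes were higher in the same library (median 2.67). Ribosome biogenesis genes had a median of 0.52 (0.33 to 0.61) over 20 members with none at 2-fold, led by Nop16 (0.79), Gnl3 (0.72), Rrs1 (0.70) and Nop2 (0.68). All 44 nuclear oxidative phosphorylation genes lay above 0, with a median of 0.40 (0.34 to 0.47), and Cycs, encoding cytochrome c, was the 1 member at 2-fold (34.9 and 78.6 FPKM, 1.15), ahead of Cox8a (0.77), Cox7a2 (0.74) and Sdhd (0.62). Glycolysis genes had a median of 0.40 (0.11 to 0.75) over 20 members, of which Pgam1 (42.7 and 171 FPKM, 1.98) and Tpi1 (35.7 and 114 FPKM, 1.65) were higher, and Slc16a3 (0.97) and Hk2 (0.95) fell short only through the pseudocount, with read ratios of 2.15 and 2.51. Tricarboxylic acid cycle genes had a median of 0.21 (0.17 to 0.38) over 18 members, with Fh1 higher (1.10) and Idh3a (0.53), Idh3g (0.51) and Sucla2 (0.41) under 2-fold. For cholesterol genes the median was 0.22 (0.04 to 0.29) over 22 members, with Fdps higher (22.2 and 64.7 FPKM) and Lss (0.58), Pmvk (0.49) and Mvk (0.46) under 2-fold. Fatty acid genes had a median of 0.35 (0.09 to 0.63) over 19 members, with Fabp5 (1.63) and Fads2 (1.45) higher and Scd2 (0.73) and Fasn (0.65) under 2-fold. Amino acid and iron uptake genes had a median of 0.33 (-0.11 to 0.79) over 11 members with none at 2-fold, among them Slc16a10 (0.82), Slc7a11 (0.79), Slc7a5 (0.48) and Slc7a1 (0.40). Proteasome subunits had a median of 0.32 (0.24 to 0.40) over 38 members with none at 2-fold, led by Psma7 (0.68), Psmb7 (0.62), Psmb5 (0.57) and Psma5 (0.55). Hypoxia genes had a median of 0.26 (-0.24 to 0.62) over 15 members with none at 2-fold, or 0.16 with a filter of 5 FPKM, the highest being Egln3 (0.89), Ddit4 (0.73), Ero1a (0.67) and Ndrg1 (0.62). Cytosolic ribosomal protein genes had a median of 0.12 (0.07 to 0.16) over 82 members, or 0.0384 as TPM, of which Rps27l was higher (1.25) and Rps27a (0.98), Rpl36 (0.68) and Rpl14 (0.55) were under 2-fold.

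Type I interferon response genes were lower as a group. All 30 members lay below 0, 13 were at least 2-fold lower, and the median was -0.95 (-1.30 to -0.85), below all 10000 random lists. With Oas2 above, the lowest were the antiviral genes Rsad2 (11.8 and 3.02 FPKM, -1.67), Ifit1 (41.7 and 12.9 FPKM, -1.62) and Oasl2 (27.5 and 8.29 FPKM, -1.61). Centred on T cell genes, the median was -0.54 (-0.86 to -0.42) and 7 members were lower. In the same library, the macrophage complement genes C1qa, C1qb and C1qc, picked after their values were seen, had log2 ratios of -0.83, -0.99 and -0.93, under 2-fold. Interferon-gamma response genes had a median of -0.47 (-0.56 to -0.14) over 26 members, near that of the T cell receptor signalling genes. In this list, the chemokine Cxcl10 (17.4 and 5.28 FPKM, -1.55) and Gbp6 (-1.05, or -0.61 centred) were lower, Gbp9 was at -0.88, and Irf8, a transcription factor of myeloid progenitors, was higher (19.1 and 76.2 FPKM, 1.94). MHC class I presentation genes had a median of -0.12 (-0.35 to 0.07) over 15 members with none at 2-fold, or 0.33 centred, with H2-Q4 at -0.44, H2-T22 at -0.40, B2m at -0.38 and Psmb9 at 0.37.

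Immediate early and heat shock genes, which handling of cells can induce, had 5 of 22 members lower and a median of -0.17 (-0.96 to 0.11), or -0.44 with a filter of 5 FPKM and 0.24 centred on T cell genes. The early T cell receptor response genes Tnfaip3, Nr4a1 and Nfkbiz were lower in the same library. Lower were the phosphatase Dusp1 (214 and 71.3 FPKM, -1.57), the AP-1 genes Fos (142 and 53.3 FPKM, -1.40) and Fosb (68.7 and 27.6 FPKM, -1.28), and Klf6 (-1.28). Of these 4, only Dusp1 stayed at 2-fold when centred (-1.12). The last of the 5, the AP-1 gene Junb, named after its value was seen, was at 1012 and 444 FPKM (-1.19, or -0.73 centred). Unfolded protein response genes had a median of 0.12 (-0.09 to 0.45) over 22 members, or 0.0449 as TPM, with Sdf2l1 (1.27) and Ern1 (1.11) higher, Dnajb9 lower (-1.14, or -0.70 centred) and Pdia6 at 0.73. Genes of p53 and apoptosis had a median of -0.18 (-0.36 to 0.13) over 22 members, or 0.21 centred. The proapoptotic genes Bid (15.2 and 38.7 FPKM, 1.29) and Bad (11.5 and 24.0 FPKM, 1.00) were higher, Bad exactly at the threshold and under it on 4 other scalings, and Pmaip1 (0.91) and Cdkn1a (0.71) were under 2-fold.

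Markers of other cell types outside the myeloid lineage were mostly under 2-fold. Centred on T cell genes, medians were 0.41 for B cell, 0.66 for plasma cell, 0.46 for NK and CD8 T cell, 0.48 for dendritic cell, 0.45 for erythroid and 0.45 for stromal genes, with 1, 2, 3, 2, 4 and 1 members higher. On that scaling the median of all genes was 0.43. B cell genes had a median of 0.02 (-0.88 to 0.84) over 7 members with none at 2-fold, or -0.04 rescaled to TPM, with Bank1 at -0.88, Cd79b at 0.84, Fcmr at -0.46 and Cd79a at 0.24. Plasma cell genes had a median of 0.24 (0.05 to 0.96) over 6 members with none at 2-fold, with Mzb1 at 0.96, Jchain at 0.69, Edem2 at 0.28 and Sdc1 at 0.19. Genes of NK and CD8 T cells had a median of 0.12 (-0.19 to 0.52) over 18 members, or 0.51 with a filter of 5 FPKM, with Gzmk higher (1.03, ended on TMM-scaled counts), Gzmm lower on 31 and 9 reads (-1.29), and Klrd1 (0.70) and Klra3 (0.69) under 2-fold. Dendritic cell genes had a median of 0.04 (-0.69 to 1.40) over 11 members, or -0.03 rescaled to TPM. In that list Flt3 and H2-DMb1 (1.40) were higher and Bst2 was at -0.74. Erythroid genes had a median of 0.08 (-0.52 to 1.11) over 12 members, with Rhd (1 and 22 reads), Klf1 (2 and 24 reads) and Car1 (16.4 and 36.7 FPKM, 1.11) higher and the hemoglobin gene Hbb-b1, one of a family of near-identical genes, lower on 11 and 0 reads. Platelet genes had a median of -0.19 (-0.61 to 0.24) over 6 members with none at 2-fold, or 0.06 centred on T cell genes, with Ppbp at -0.61, Pf4 at -0.45, Gp9 at -0.24 and Itga2b at 0.24. Stromal and endothelial genes had a median of 0.04 (-0.11 to 0.31) over 11 members, or -0.02 rescaled to TPM, with Pdgfrb higher (1.10) and Col3a1 (0.31), Cxcl12 (0.30) and Col1a1 (0.14) under 2-fold. The list of mitochondrially encoded genes was written as a symbol prefix that matched 0 symbols, so it gave no value.

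**Figure D3:**
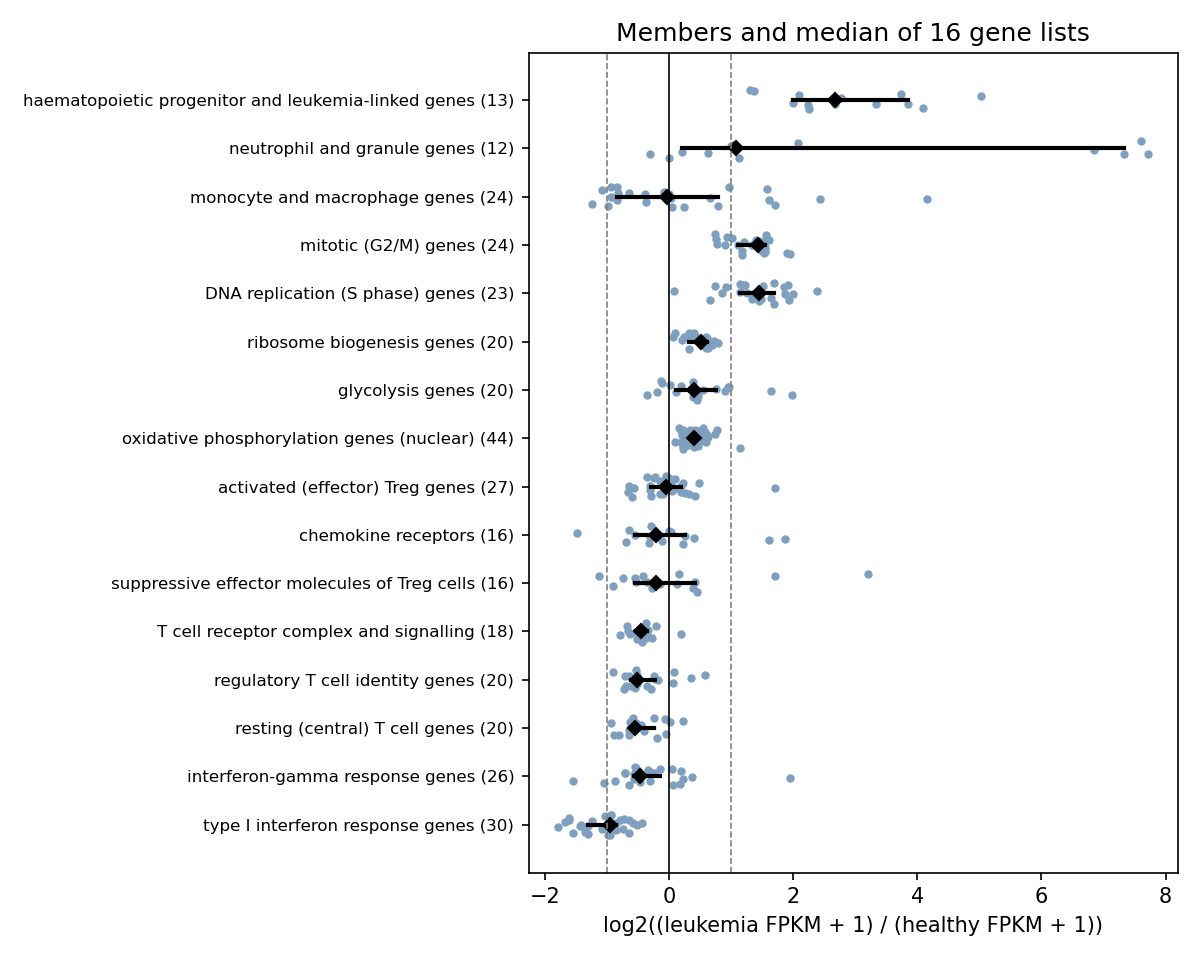
Log2 ratios of leukemia over healthy FPKM for members of 16 gene lists (points), with the median (diamond) and its 95% order-statistic interval over members (bar), and the number of members in parentheses; dashed lines mark 2-fold. Progenitor genes (median 2.67) and cell division genes (1.43 and 1.45) lie to the right, and type I interferon response genes (-0.95) to the left.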

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

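The scaling centred on T cell genes and the condition on the read-ratio interval were chosen after seeing the data, the others were not. The count of genes higher in leukemia, 898, stayed between 821 and 1245 in 7 of 9 alternatives. It was 590 with a filter of 5 FPKM, which tests fewer genes, and 1805 when centred on T cell genes, which raises every leukemia value. The 958 genes higher on TMM-scaled counts shared 785 with the 898. The lower genes depended more on the processing. From 267 they went to 493 with a pseudocount of 0.1 FPKM, 414 as TPM, 405 without other-cell genes and 135 with a filter of 5 FPKM. They numbered 155 when centred on T cell genes and 169 when the interval had to leave out 1. Of the 235 lower on TMM-scaled counts, 150 were among the 267. The TMM factors were 0.995 in healthy and 1.006 in leukemia, so the scaling itself moved values little. That alternative also used counts not divided by gene length, with a pseudocount of 1 CPM in place of 1 FPKM. The separate effects of these changes were not tested. Dropping the filter on low values removed or added no call, so it tests nothing about the calls. It could change a list median only where a list had members under 1 FPKM. Among these, the progenitor median went from 2.67 to 2.25, histones from 0.80 to 0.46 and chemokine receptors from -0.20 to -0.06. Of the lists whose interval had left out 0, the medians of 5 turned positive when centred on T cell genes: costimulatory receptors 0.0874, adhesion and homing 0.143, early T cell receptor response 0.0726, interleukin-2 and STAT5 0.144, and TGF-beta 0.0014; this follows from the centring factor of 0.730. Other list medians that left their interval when centred on T cell genes were Treg identity -0.0813, resting T cell -0.0981, T cell receptor signalling -0.0026, conventional CD4 T cell -0.0357, interferon-gamma -0.0272 and type I interferon -0.54. Further ones were activated Treg 0.40, lineage factors 0.22, MHC class I 0.33, p53 and apoptosis 0.21, immediate early 0.24, unfolded protein response 0.56, hypoxia 0.64, stromal 0.45, mitotic 1.85 and DNA replication 1.89. In metabolism and synthesis these were glycolysis 0.85, oxidative phosphorylation 0.85, tricarboxylic acid cycle 0.65, cholesterol 0.64, fatty acid 0.76, ribosome biogenesis 0.95, proteasome 0.77 and ribosomal proteins 0.57. As TPM, oxidative phosphorylation was 0.33, tricarboxylic acid cycle 0.13 and ribosomal proteins 0.0384. Without other-cell genes these were 0.33, 0.14 and 0.0417. Resting T cell genes were then at -0.63, but over 13 members instead of 20, since conventional CD4 T cell genes counted as other-cell genes. Histone genes were at 1.40 with a pseudocount of 0.1 FPKM. The other 300 list medians over all alternatives stayed within their intervals, among them no-filter medians that could not change. Some intervals were wide. The neutrophil median was 1.08, 3.03 with a pseudocount of 0.1 FPKM, 7.09 over 6 members with a filter of 5 FPKM, and 0.78 over 17 with no filter. The immediate early median was -0.44 with the filter of 5 FPKM. The unfolded protein response median was 0.0449 as TPM and 0.0476 without other-cell genes. Of 88 calls among named genes, at most 5 were lost with the pseudocount of 0.1 FPKM, TPM, median ratio or TMM scaling. When centred, 11 were lost and 31 added. Only 75 of the calls were measured with the filter of 5 FPKM, which changes no value and so could lose none of these. Without other-cell genes 67 were measured, of which 1 was lost. At this depth, a gene with 10 reads in each library leaves ratios from 0.375 to 2.69 open, so a 2-fold difference was not resolved for a gene with so few reads.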

Other observations

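All tests in this part were chosen after the values were seen, and so were the genes of this and the next paragraph. These genes stand for no list that was tested. Of genes known from red pulp macrophages of the spleen, the transcription factor Spic was at 40.1 FPKM in healthy and 17.3 FPKM in leukemia (log2 ratio -1.17), the mannose receptor Mrc1 at 27.5 and 9.91 FPKM (-1.39), Fcna at 95.4 and 41.6 FPKM (-1.18), Itgad at 22.6 and 8.82 FPKM (-1.27), and heme oxygenase, Hmox1, at 151 and 71.0 FPKM (-1.08). Centred on T cell genes, these were at -0.74, -0.97, -0.73, -0.85 and -0.63, all under 2-fold. The fixed monocyte and macrophage list went both ways, with 12 members above and 12 below 0. The complement genes C1qa, C1qb and C1qc were at 173, 165 and 167 FPKM in healthy and at 96.6, 82.9 and 87.4 FPKM in leukemia.

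Of single transcription factor genes, Lmo2 was at 3.48 and 79.2 FPKM, Lyl1 at 1.98 and 48.3 FPKM, Nfe2 at 1.37 and 28.8 FPKM and Erg at 0.33 and 11.6 FPKM, while Hlf and Mecom of the progenitor list were not higher. Among chemokines, Ccl9 was at 1.78 and 44.4 FPKM and Ccl3 at 2.86 and 23.4 FPKM. Also higher were Dmrtb1, on 1 and 289 reads, and the glutamate receptor gene Gria3, at 0.16 and 15.6 FPKM. Sprr2a1 was at 0.02 and 17.5 FPKM, but its near-identical copies Sprr2a2 (log2 ratio -0.61) and Sprr2a3 (0.04) make its value uncertain. Among dual-specificity phosphatases, Dusp4 (-1.52) and Dusp5 (-1.43) were lower with Dusp1 (-1.57), while Dusp2 (-0.08) and Dusp6 (0.22) were not; centred on T cell genes, Dusp5 was under 2-fold (-0.99).

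The granule and progenitor genes may, as a hypothesis, come from RNA of leukemia cells or other myeloid progenitors in the sorted sample. The gate for CD4 and FOXP3-GFP selects against such cells. It also selects against macrophages, yet the macrophage gene C1qa stood at 173 FPKM in the healthy library. Added RNA would dilute T cell transcripts, and the T cell receptor signalling list had a median of -0.45 (-0.54 to -0.36), while Mpo reached 357 FPKM; of the 12 neutrophil and 13 progenitor genes, 5 and 3 reached 1 FPKM in the healthy library, and 1 of each list was in another list. Mature neutrophils as the source are argued against by 20 reads in all on 7 genes of later neutrophil stages, beside 13956 on Mpo, Elane, Prtn3 and Ctsg, and macrophages by C1qa, C1qb and C1qc, whose read ratios reached at most 0.832 when centred on T cell genes; monocytes stay open, with a centred median of 0.38 (-0.41 to 1.23) for the monocyte and macrophage list, whose members went both ways. A female origin of the added RNA is a candidate explanation for Xist, the X-inactivation RNA, at 0.58 and 14.5 FPKM (read ratio 27.6, 22.3 to 34.9), beside a median of -0.37 (-0.79 to 0.52) over 7 Y-linked genes, near that of the T cell genes but with an interval that holds 0. A female host within the leukemia sample was not tested, nor was expression of these genes by Treg cells themselves, and both stay open.

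Dilution of T cell RNA alone is argued against for the lower type I interferon response genes, since the list's median of -0.95 has an upper bound of -0.85, below the lower bound of -0.54 of the T cell receptor signalling list. Fewer macrophages in the leukemia sample may contribute. A gate for CD4 and FOXP3-GFP selects against macrophages, yet C1qa, C1qb and C1qc stood at 173, 165 and 167 FPKM in the healthy library. The gate is therefore no argument against this explanation. The median of C1qa, C1qb and C1qc was -0.93, inside the interval of the interferon list. Fewer macrophages and a weaker interferon response in Treg cells cannot be told apart in 1 mixed library per group.

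For the mitotic genes, a median 1.88 above that of the T cell receptor signalling list leaves open whether the dividing cells were Treg cells or, as a hypothesis, cells of the progenitor type. These cannot be told apart, since bulk RNA of 1 library does not assign transcripts to cells.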
